A study of Mus musculus with 15 samples.

How the data were processed

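Liver RNA of 15 samples of mice aged 16 months was measured on Affymetrix arrays: 6 tumours and 6 non-tumorous livers of Mdr2 (Abcb4) knockout mice and 3 livers of heterozygous control mice. The values deposited by the authors are signals of intensity per probe set made with MAS5, on a linear scale, with each array scaled to about the same trimmed mean. The version of MAS5 and its settings were not stated and no detection calls were used. In the table the trimmed means, with 2% of values left out at each end, lay near 150 on every array. The table held 22690 probe sets, of which 64 controls were left out.

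Probe sets were tied to genes with the probe annotation: 20393 had 1 gene, 691 had several and were not used for genes, and 1606 were not listed. Gene symbols were compared with a RefSeq gene table of assembly GRCm38.p6, which held the gene of 20364 probe sets and changed 0 symbols; the order of genes along chromosomes came from that table. Signals were transformed as log2 of the signal plus 9.1, the 20th percentile of all signals. The fold of a gene close to background is therefore smaller than the ratio of its signals, and a gene is said to be close to background in a group where no array of the group had it above its 40th percentile. Probe sets above the 40th percentile in at least 3 arrays were kept, 16120 in all, of which 14796 had 1 gene, and each gene was represented by its probe set with the highest mean, giving 9528 genes. The number of arrays limits the precision.

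Groups and animals were taken from the labels. The labels tie tumours to livers of 4 mice, 2 of which gave 2 tumours each. In a check of this pairing, correlations between samples of 1 animal, after group means were taken out, lay between -0.158 and 0.0852. Taking out group means pulls correlations within a group below 0. Among pairs of tumours, the pairs of 1 mouse had the highest values, -0.054 for 5-1 with 5-2 and 1.01e-04 for 6-1 with 6-2, against -0.352 to -0.087 for the others, and no test was run on this. Pairs of a liver and a tumour of 1 mouse did not stand out. They lay between -0.158 and 0.0852, against -0.101 to 0.171 for livers and tumours of different mice. The matching of livers to tumours therefore rests on the labels. At most 122 of the 22690 signals, as deposited, were exactly equal between any 2 arrays.

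All 15 arrays were fitted together with limma 3.58.1 (statmod 1.5.0, R 4.3.3), with lmFit and eBayes with a trend, and with the animal as a random block through duplicateCorrelation, whose consensus correlation was -0.0175. At a correlation so close to 0 the block hardly changes the fit. Tumours of the same mouse therefore count nearly as samples of separate animals. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called. The 3 comparisons were non-tumorous knockout livers against controls, tumours against non-tumorous knockout livers, and tumours against controls. The groups, tests, gene lists, rule for naming genes and alternatives were chosen before the data were examined, except where the text says otherwise.

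The 29 gene lists were tested with cameraPR on the moderated statistics with a preset correlation between genes of 0.01, adjusted over the lists within each comparison, and again with an estimated correlation. With the preset correlation 14, 11 and 17 lists were called in the 3 comparisons, and with the estimated one 0, 2 and 2. Members were also counted when adjusted over the list alone. Some genes are in more than 1 list.

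Genes were named by a rule. For each comparison, among called genes whose values did not overlap between the groups, the 12 largest rises and the 10 largest falls were named, leaving out symbols of clones and gene models. Abcb4 was added, as were up to 4 members of each list, the 2 largest rises and 2 largest falls among called members, or the brightest member where none was called. Values per sample were given for a short set of genes fixed in the same way, and some items of that set were not analysed here. Values per sample of some other genes, such as Cyp2e1 and Eif2s3y, were given as well and were outside that set.

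For stretches of neighbouring genes, each sample's log2 ratio to the mean of the knockout livers (for a knockout liver, of the others) was limited to between -1 and 1, centred on the sample's median and averaged over windows of 41 genes along the 9511 genes with a place in the gene order. The limit was the 95th percentile of the largest absolute window mean in 1000 permutations of the genes. The spread of groups and the overlap of lists of changed genes were described without a test. Ratios of 3' to 5' signal of actin and Gapdh probe sets were compared between groups with exact two-sided permutation tests.

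The fits were tested on simulated data without real differences other than 100 planted changes of log2 1 and 100 of log2 2. With the SD of each gene taken within each group, the fits recovered 43%, 67% and 40% of the changes of log2 1 and 88%, 97% and 91% of those of log2 2 in the 3 comparisons, with 10.3%, 8.89% and 16.6% false among the calls, above the nominal share. A second version with SDs pooled over groups was added after these results were seen; it recovered 50%, 72% and 41%, and 94%, 98% and 93%, with 0%, 6.08% and 4.29% false. Lists were tried for tumours against knockout livers alone, where a moved list was found and 0 other lists were called in both versions. The simulated genes were drawn independently of each other, so this trial cannot show whether the preset correlation suits genes that vary together. With no planted stretch 0 genes lay in windows past the limit, and with 100 neighbouring genes lowered, 100 of them and 13 others did. The values for this trial were 1 shuffle of the ratios of tumour 3, and the limit also came from shuffled genes. A count near 0 without a stretch was therefore built in. It does not cover false stretches from neighbouring genes that vary together. The simulation of shared controls was made in both versions in the same order.

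Alternatives were no block, the animal as a fixed term in matched animals, averaging of the tumours of 1 animal, quantile normalization, arrays centred on their medians, no pseudocount and a pseudocount of 28.8 (the 40th percentile), no filter and one at the 60th percentile, the mean of a gene's probe sets, all kept probe sets, array weights, fits of the compared groups alone, an adjusted p under 0.01, a 2-fold minimum, windows of 81 genes, ratios to the liver of the same animal, and leaving out each array in turn. A covariate for the actin 3' to 5' ratio was added after the values were seen.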

Results

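Gene expression was measured with Affymetrix arrays in 15 mouse liver samples of 16 months of age. The Mdr2 gene, whose current symbol is Abcb4, encodes the transporter that moves phosphatidylcholine from hepatocytes into bile. The samples were 6 liver tumours and 6 non-tumorous livers of Mdr2-knockout mice and 3 livers of heterozygous control mice. By the labels, 4 of the 6 knockout mice gave both tissues: tumours 3 and 4 came from the mice of non-tumorous livers 3 and 4, tumours 5-1 and 5-2 from the mouse of liver 5, and tumours 6-1 and 6-2 from the mouse of liver 6. Each array held 22690 probe sets with a median signal between 35.8 and 51.2, and 9528 genes were tested. The number of arrays limits the precision of each value below.

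Abcb4 itself, taken first as a check of the labels, had a mean signal of 890 ± 114 (SD, n = 3) in the controls and of 236 ± 46.2 (SD, n = 6) in the non-tumorous knockout livers. The gene was 3.70-fold lower in these livers than in the controls (log2 change -1.89 ± 0.36 SE, n = 6 and 3, adjusted p = 0.0143), below every control in 6 of 6 livers. This call was lost without any 1 of the controls, with an adjusted p of 0.0874 without control 1, 0.0516 without control 2 and 0.0742 without control 3, at log2 changes of -1.80, -1.98 and -1.89. In the tumours Abcb4 was 3.38-fold lower than in the controls (log2 change -1.76 ± 0.36 SE, n = 6 and 3, adjusted p = 0.00780), with a mean signal of 302 ± 208 (SD, n = 6). That call was lost with these groups alone in the fit (log2 change -1.69, adjusted p = 0.0826) and with the covariate for RNA quality described with the comparisons (-0.81, adjusted p = 0.622), which also ended the call in the non-tumorous livers (-1.21, adjusted p = 0.310). Tumour 4 had the highest Abcb4 signal of a knockout sample, 681, and tumour 5-1 the lowest, 123. A single probe set measured Abcb4, and its place relative to the disrupted part of the gene is unknown, so its values may not test the genotype. The controls are heterozygous, so the values do not give the level of a mouse with 2 intact copies.

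The comparison of non-tumorous knockout livers with control livers asks how non-tumorous tissue of knockout livers differs from control liver at the same age. By the labels, 4 of the 6 knockout mice also gave tumours. Effects of the genotype and of a tumour in the same liver are therefore not separated here. Anxa5, a protein that binds phosphatidylserine on membranes, was 21.8-fold higher in the knockout livers (log2 change 4.44 ± 0.26 SE, n = 6 and 3, adjusted p = 1.41e-08), with a mean signal of 1029 ± 184 against 40.2 ± 19.4 (SD). Ly6d, a small cell surface protein, rose 17.1-fold (log2 change 4.09 ± 0.65 SE, adjusted p = 0.00320) and Tinag, a basement membrane protein, rose 9.97-fold (3.32 ± 0.45 SE, adjusted p = 0.00123). Hsd3b5, a steroid dehydrogenase known to be higher in male than in female mouse liver, was 32.1-fold lower (log2 change -5.01 ± 1.03 SE, n = 6 and 3, adjusted p = 0.0201), and Dio1, which activates thyroid hormone, was 7.53-fold lower (-2.91 ± 0.68 SE, adjusted p = 0.0378). Of 9528 genes, 160 passed the test: 130 were higher and 30 lower in the knockout livers, and 127 of them differed at least 2-fold.

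Among the other genes with the largest changes, Ifi27l2b (log2 change 2.78), Tnfrsf12a (2.73), a receptor of the TNF family, and Lgals1 (2.69), a galectin, rose in the knockout livers. So did Mcm6 (2.61, with a second probe set, not called, at 1.05), part of the DNA replication helicase, Lpl (2.58), lipoprotein lipase, and Omd (2.50). Each of these genes had an SE between 0.26 and 0.60. Emilin1 (2.66, with a second probe set at 0.85), of elastic fibres, Mapt (2.48), a microtubule protein, and Lcn2 (3.30 ± 0.82 SE, adjusted p = 0.0483), an acute-phase protein that binds iron carriers, rose as well. Lower were Cnmd (-2.23), Susd4 (-2.15), Ces1e (-2.10), a carboxylesterase, Cyp2b9 (-2.02), a cytochrome P450, Gna14 (-1.90), Tmem216 (-1.79) and Sult5a1 (-1.78 ± 0.21 SE, adjusted p = 0.000226), a sulfotransferase. Ly6d, Tinag, Emilin1 and Mapt, and of the genes named from lists Ccnb2, Col5a2, Abcb1b and Cdkn1a, were close to background in the controls, and Cyp2b9 and Gna14 in the knockout livers. Their folds are set in part by the constant added before taking logarithms and are not exact ratios. The change of Ly6d was 5.47 with no constant and 3.06 with a larger one, and that of Hsd3b5 was -5.48 and -4.54, where the call of Hsd3b5 was lost with no constant (adjusted p = 0.0651).

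**Figure D1:**
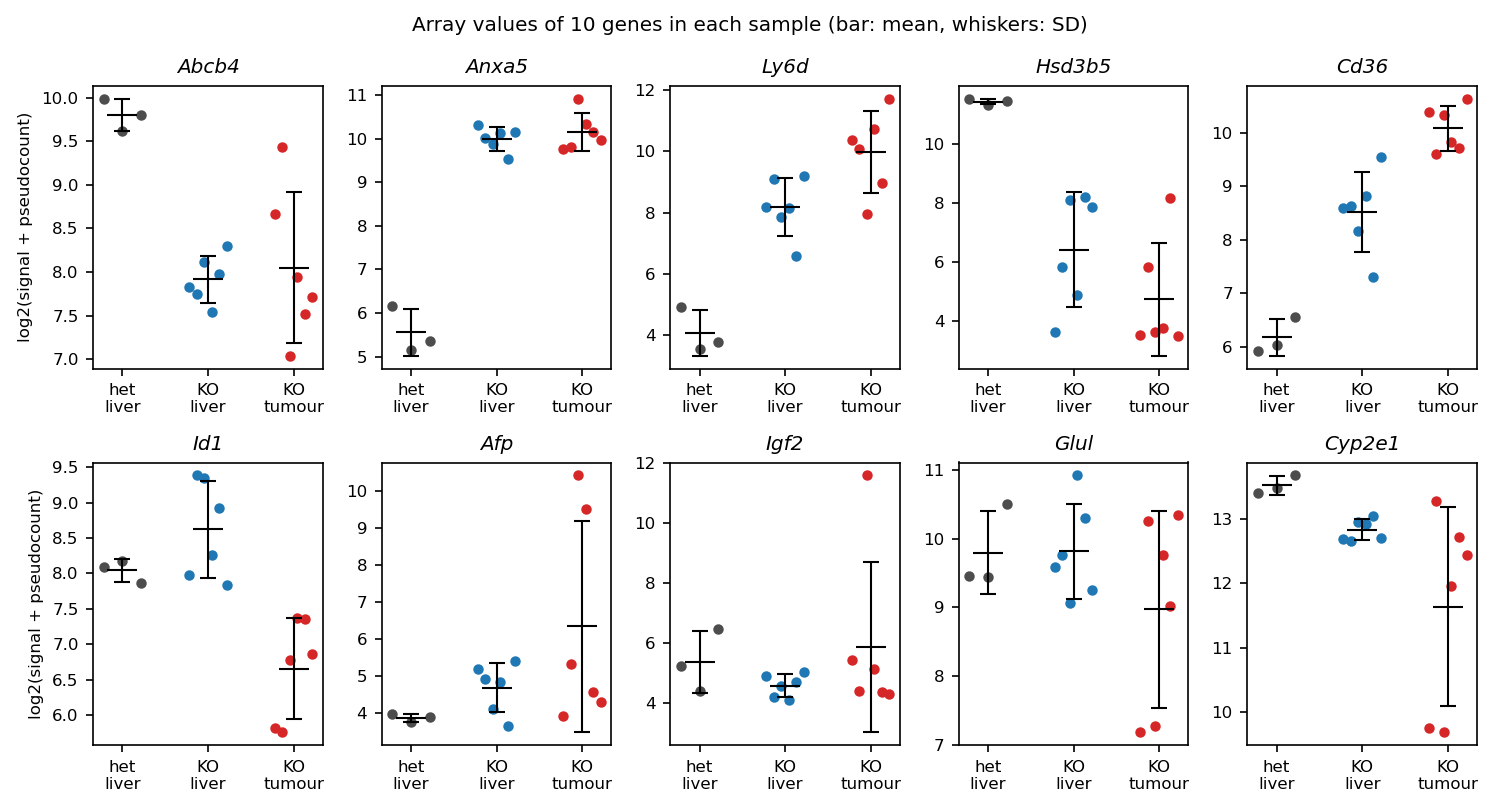
Values of 10 genes in each of the 15 arrays, as log2 of the signal plus the pseudocount, by group (control livers, n = 3; non-tumorous knockout livers, n = 6; tumours, n = 6); points are arrays and the bar with whiskers is the mean ± SD. Anxa5 and Ly6d were higher, and Abcb4 and Hsd3b5 lower, in 6 of 6 non-tumorous knockout livers than in the 3 controls, while Afp was high in tumours 5-1 and 5-2 and Igf2 in tumour 5-1.

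Genes of cell division were higher in the knockout livers. Of 28 tested genes of S phase and mitosis, 6 rose and 0 fell, and 12 rose when adjusted over the list alone (median log2 change 0.73, adjusted p = 5.18e-08, adjusted p = 0.164 with an estimated correlation). Examples are Mcm6 and Ccnb2, a mitotic cyclin (log2 change 1.82 ± 0.43 SE, adjusted p = 0.0419). Of 23 proto-oncogenes, tumour suppressors and growth factor receptors, 4 rose and 0 fell, and 8 rose when adjusted over the list alone (median 0.08, adjusted p = 0.00295, adjusted p = 0.164 with an estimated correlation). Both examples of that list act on the cell cycle: Cdkn2c, an inhibitor of cyclin-dependent kinases (2.40 ± 0.24 SE, adjusted p = 2.69e-05), and Ccnd1, cyclin D1 (2.14 ± 0.45 SE, adjusted p = 0.0224). The p53 target list did not pass (median 0.19, adjusted p = 0.0503), although Cdkn1a, a kinase inhibitor (1.76), and Btg2 (1.35) passed singly. A second Cdkn1a probe set gave -0.27.

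Genes of matrix, macrophages and bile ducts were higher as well, and lists of neutrophils, T and NK cells and B and plasma cells did not pass. Of 32 matrix genes, 3 rose and 0 fell, and 12 rose when adjusted over the list alone (median log2 change 0.87, adjusted p = 2.30e-07, adjusted p = 0.319 with an estimated correlation). Among the 3 were Lum (1.95 ± 0.48 SE, adjusted p = 0.0472) and the collagen Col5a2 (1.83 ± 0.44 SE, adjusted p = 0.0442). Of 21 macrophage markers, 2 rose and 0 fell, and 7 rose when adjusted over the list alone (median 0.71, adjusted p = 0.000109, adjusted p = 0.319 with an estimated correlation). They were Lyz2, lysozyme (2.06 ± 0.46 SE, adjusted p = 0.0313), and Cd68 (1.67 ± 0.25 SE, adjusted p = 0.00213). Of 16 bile duct markers, 1 rose, Cdh1 (1.97), which periportal hepatocytes also express. In all, 6 rose and 1 fell when adjusted over the list alone (median 0.73, adjusted p = 0.00173, adjusted p = 0.164 with an estimated correlation). Of 19 inflammation genes, Tnfrsf12a alone rose (median 0.44, adjusted p = 0.00403, adjusted p = 0.414 with an estimated correlation). Of 20 interferon-stimulated genes, Usp18 (1.48) alone rose (median 0.45, adjusted p = 0.0157, adjusted p = 0.453 with an estimated correlation). The MHC class II list was called with 0 of 7 genes past the test, 1 when adjusted over the list alone (median 0.89, adjusted p = 0.0214, adjusted p = 0.440 with an estimated correlation). Its brightest gene, H2-Aa, was at 1.22 (adjusted p = 0.254). The endothelium list (median 0.25, adjusted p = 0.0572) and the stellate cell list (median 0.24, adjusted p = 0.189) did not pass, although Pdgfrb (1.51) of the latter passed singly.

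Lipogenesis, oncofetal and antioxidant genes were higher as lists, and hepatocyte, fat oxidation and male liver genes were lower. Of 25 lipogenesis genes, 1 rose, and 7 rose and 1 fell when adjusted over the list alone (median log2 change 0.19, adjusted p = 0.0227, adjusted p = 0.591 with an estimated correlation). The gene was Cd36, a fatty acid transporter (2.34 ± 0.35 SE, adjusted p = 0.00213). Of 19 oncofetal genes, 3 rose, among them Ly6d and Lpl (median 0.27, adjusted p = 0.0263, adjusted p = 0.383 with an estimated correlation). The antioxidant list was called with 0 of 25 genes past the test (median 0.30, adjusted p = 0.0172, adjusted p = 0.319 with an estimated correlation). Its brightest gene, Gstm1, was at 0.06. Hepatocyte proteins and transcription factors were lower as a list of 36 genes with 0 past the test in limma (median -0.24, adjusted p = 0.00235, adjusted p = 0.319 with an estimated correlation). With quantile normalization that median was -0.060 and the call was lost (adjusted p = 0.222). Lower as well were 24 fat oxidation genes, also with 0 past the test (median -0.26, adjusted p = 0.0263, adjusted p = 0.453 with an estimated correlation). That call was lost with quantile normalization (-0.19, adjusted p = 0.102) and with arrays centred on their medians (-0.30, adjusted p = 0.0510). Of 12 genes higher in male than in female liver, Hsd3b5 and Susd4 fell, and 4 fell when adjusted over the list alone (median -0.72, adjusted p = 0.00652, adjusted p = 0.440 with an estimated correlation). Of the bile list, the drug transporters Abcb1b (1.99) and Abcb1a (1.51) rose and Abcb4 fell, and the list did not pass (26 genes, median -0.25, adjusted p = 0.0553). Gstm3 (2.01) of the beta-catenin list rose together with Ccnd1, and that list did not pass (22 genes, median -0.42, adjusted p = 0.199).

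Other lists below the threshold were drug metabolism (31 genes, median -0.13, adjusted p = 0.0572), cholesterol synthesis (18 genes, 0.50, adjusted p = 0.103), neutrophils (9 genes, -0.26, adjusted p = 0.160), blood and other tissues (8 genes, -0.22, adjusted p = 0.199) and periportal genes (15 genes, -0.21, adjusted p = 0.237). The T and NK cell list was at -0.04 (9 genes, adjusted p = 0.503), the B and plasma cell list at 0.05 (7 genes, adjusted p = 0.741), the list of genes higher in female liver at -0.07 (9 genes, adjusted p = 0.713), the X- and Y-linked list at -0.14 (4 genes, adjusted p = 0.713) and the acute-phase list, of which Lcn2 alone rose, at -0.07 (25 genes, adjusted p = 0.860). Medians and means had opposite signs for the acute-phase list (mean 0.10) and the B and plasma cell list (mean -0.01).

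A measure of RNA quality was set beside this comparison. The ratio of 3' to 5' signal of actin, which rises as RNA degrades, was 2.99 ± 0.414 (SD, n = 3) in the controls, 2.09 ± 0.393 (SD, n = 6) in the knockout livers and 1.78 ± 0.208 (SD, n = 6) in the tumours (knockout livers against controls, exact two-sided permutation p = 0.0357, adjusted p = 0.0714 over 6 tests). This ratio and that of Gapdh (exact permutation p = 0.0595, adjusted p = 0.0893) did not pass after adjustment. With 3 controls there are only 84 splits, so not passing does not show that the ratios are alike. With the actin ratio as a covariate, an alternative chosen after the values were seen, 21 genes passed. The lists of male liver, MHC class II, oncofetal, interferon, hepatocyte and fat oxidation genes lost their calls, the first at a median of 0.08, the second at -0.11 and the third at -0.18. The medians of interferon (0.30), hepatocyte (-0.13) and fat oxidation genes (-0.032) kept their direction.

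Leaving out single arrays moved the count of 160 genes. It was 34, 48 and 41 without controls 1, 2 and 3, and 86, 85, 71, 65 and 100 without knockout livers 1, 2, 3, 4 and 6. Without tumour 4 it was 252, and without tumour 5-1 it was 298, since all groups share 1 estimate of the spread. Fitted with these groups alone it was 994. Of the 37 genes named by the rule and called here (Abcb4 apart), 13 kept their call in every fit without 1 array: Anxa5, Ly6d, Tinag, Ifi27l2b, Tnfrsf12a, Lgals1, Emilin1, Mapt, Sult5a1, Cdkn2c, Cdh1, Cd36 and Cd68. Without controls 1, 2 and 3, 22, 23 and 22 of the 37 calls were lost, without knockout livers 1, 2, 3, 4, 5 and 6, 14, 14, 17, 18, 1 and 14, and without tumour 5-2, 1. Of the 14 lists, 10 kept theirs; fat oxidation lost it without knockout livers 1 and 3 (adjusted p = 0.0809 and 0.0545), oncofetal without knockout liver 3 (0.0510), lipogenesis without control 1 (0.0653) and MHC class II without control 2 (0.0771). A stricter filter on dim probe sets ended the calls of lipogenesis (median 0.11, adjusted p = 0.172) and MHC class II (0.93, adjusted p = 0.0704), and no filter that of oncofetal genes (0.20, adjusted p = 0.0628). The values of 1409 genes, 14.8%, did not overlap between the groups, against 2.38% by chance.

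The comparison of tumours with non-tumorous livers of the same genotype gave few single genes. Id1 and Id3, inhibitors of basic helix-loop-helix transcription factors that BMP signalling induces, were 3.90-fold and 2.96-fold lower in the tumours (log2 changes -1.96 ± 0.32 and -1.57 ± 0.25 SE, n = 6 and 6, adjusted p = 0.0342 for both). Ntrk2, a neurotrophin receptor, was 4.12-fold lower (-2.04 ± 0.38 SE, adjusted p = 0.0426). Cd36 was 2.97-fold higher (1.57 ± 0.29 SE, n = 6 and 6, adjusted p = 0.0426) and Ybx3, a cold shock domain protein, 1.76-fold higher (0.82 ± 0.14 SE, adjusted p = 0.0426; a second probe set gave 0.26). In all, 13 of 9528 genes passed the test, 2 of them higher and 11 lower. The others, all lower, were Dpep1 (-1.55), a dipeptidase close to background in the tumours, Nat8f1 (-1.29), Nfix (-1.06, with the weakest of its 5 probe sets at -0.0028), a transcription factor, Zfpm1 (1.99-fold lower), Slc38a3 (-0.87), an amino acid transporter of periportal hepatocytes, Macrod1 (-0.80), Pipox (-0.76) and Ctdsp1 (-0.63). Abcb4 did not differ by more than its error (0.13 ± 0.30 SE, adjusted p = 0.924).

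These 13 calls depended on single arrays and on which samples were fitted. Without tumour 6-1 the count was 62; it was 8 without knockout liver 6 and 8 without tumour 5-1, 5 without tumour 5-2, 3 without knockout liver 1, and 0 in limma without controls 1, 2 or 3, knockout livers 2, 3, 4 or 5, or tumours 3, 4 or 6-2, with 860 to 1098 genes at an unadjusted p under 0.05 in these fits. With the animal as a fixed block in the 4 matched animals, limma called 0 genes, with 731 genes at an unadjusted p under 0.05, and with both groups alone it called 0, with 879 at an unadjusted p under 0.05; the fit reported here had 985. With the actin covariate it also called 0; the log2 changes of the 13 genes had a median of 1.02 of those without it, 13 of 13 had the same sign, and the median SE went from 0.19 to 0.21. None of the 13 genes kept its call in every fit without 1 array.

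As lists, hepatocyte proteins, periportal genes, genes higher in male liver and beta-catenin targets were lower in the tumours. Of 36 hepatocyte genes, 0 passed singly and 10 fell when adjusted over the list alone (median log2 change -0.30, adjusted p = 1.42e-11, adjusted p = 0.00613 with an estimated correlation). Apoa1, apolipoprotein A1, was at -0.27 (adjusted p = 0.517). Of 15 periportal genes, 5 fell when adjusted over the list alone (median -0.59, adjusted p = 5.57e-08, adjusted p = 0.0329 with an estimated correlation). Cyp2f2 was at -0.67. These 2 lists passed with both correlations. With the preset correlation both calls held without any 1 array, and the estimated correlation was not tried without single arrays. Of 12 genes higher in male liver, 5 fell when adjusted over the list alone (median -1.09, adjusted p = 1.09e-06, adjusted p = 0.187 with an estimated correlation). Gstp1 was at -0.34. Of 22 beta-catenin targets, many of them pericentral, 0 passed either way (median -0.66, adjusted p = 9.89e-06, adjusted p = 0.239 with an estimated correlation). Cyp2e1, a pericentral cytochrome P450, was at -1.19 (adjusted p = 0.407). Lists of other hepatocyte functions did not pass: fat oxidation (median -0.08, adjusted p = 0.766), drug metabolism (-0.05, adjusted p = 0.261), bile (-0.13, adjusted p = 0.458), cholesterol synthesis (-0.21, adjusted p = 0.506) and the acute phase (0.03, adjusted p = 0.766).

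Markers of 3 other cell types were lower in the tumours as lists, and lists of S phase and mitosis, antioxidant, interferon and oncofetal genes were higher. Of 19 endothelium genes, 1 fell when adjusted over the list alone (median log2 change -0.25, adjusted p = 0.0198, adjusted p = 0.405 with an estimated correlation), and Fcgr2b was at -0.83. Of 14 stellate cell genes, 1 fell when adjusted over the list alone (median -0.40, adjusted p = 0.0312, adjusted p = 0.405 with an estimated correlation), and Reln was at -1.30. Of 16 bile duct genes, 2 fell when adjusted over the list alone (median -0.38, adjusted p = 0.0366, adjusted p = 0.390 with an estimated correlation), and Tm4sf4 was at -0.03. Genes of S phase and mitosis were higher as a list of 28, with 1 rise when adjusted over the list alone (median 0.47, adjusted p = 0.000163, adjusted p = 0.390 with an estimated correlation). Pcna, the brightest of them, was at -0.11. Antioxidant genes were higher too, with 2 of 25 past the test when adjusted over the list alone (median 0.20, adjusted p = 0.00926, adjusted p = 0.280 with an estimated correlation). So were 20 interferon-stimulated genes, 0 of them past either adjustment (median 0.26, adjusted p = 0.0165, adjusted p = 0.482 with an estimated correlation), with Bst2 at -0.14. Of 19 oncofetal genes, 2 rose when adjusted over the list alone (median 0.21, adjusted p = 0.0366, adjusted p = 0.390 with an estimated correlation), and Aldh1a1 was at 0.20. The macrophage list (median 0.01), the matrix list (median -0.18) and the T and NK cell list (median 0.29) did not pass (adjusted p = 0.859, 0.261 and 0.194), nor did the neutrophil list (median 0.17, adjusted p = 0.449) and the B and plasma cell list (median -0.01, adjusted p = 0.431). The macrophage list had a mean of -0.11, opposite in sign.

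The actin covariate ended the calls of the stellate and oncofetal lists (medians -0.39 and 0.12, adjusted p = 0.138 and 0.240). Array weights ended those of the bile duct and stellate lists (medians -0.26 and -0.32, adjusted p = 0.103 and 0.125). A stricter filter on dim probe sets ended the calls of the bile duct list (median -0.20, adjusted p = 0.243) and the interferon list (0.16, adjusted p = 0.0583), a pseudocount at the 40th percentile that of the bile duct list (-0.23, adjusted p = 0.0518), and no pseudocount that of the oncofetal list (0.21, adjusted p = 0.0717). With the tumours of 1 mouse averaged, the interferon and oncofetal lists lost their calls (adjusted p = 0.0947 for both). Calls of 6 of these 11 lists were lost without single arrays. Stellate was lost without knockout livers 3 and 6 and tumour 4 (medians -0.15, -0.38 and -0.25, adjusted p = 0.206, 0.0798 and 0.137). Endothelium was lost without tumours 4 and 6-1 (medians -0.12 and -0.11, adjusted p = 0.0906 and 0.188). Antioxidant was lost without tumour 3 (median 0.20, adjusted p = 0.0827), and interferon without knockout liver 5 and tumour 6-2 (medians 0.19 and 0.18, adjusted p = 0.0855 and 0.114). Bile duct was lost without knockout livers 1 and 4 and tumours 3, 4 and 6-2 (adjusted p = 0.0689, 0.0548, 0.288, 0.0757 and 0.0508). Oncofetal was lost without knockout livers 4, 5 and 6 and tumours 5-1, 5-2 and 6-2 (adjusted p = 0.0518, 0.0855, 0.0674, 0.182, 0.223 and 0.0652). Its medians in these fits were 0.33, 0.26, 0.27, 0.14, 0.23 and 0.28. The values of 66 genes, 0.693%, did not overlap between the groups, against 0.216% by chance.

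**Figure D2:**
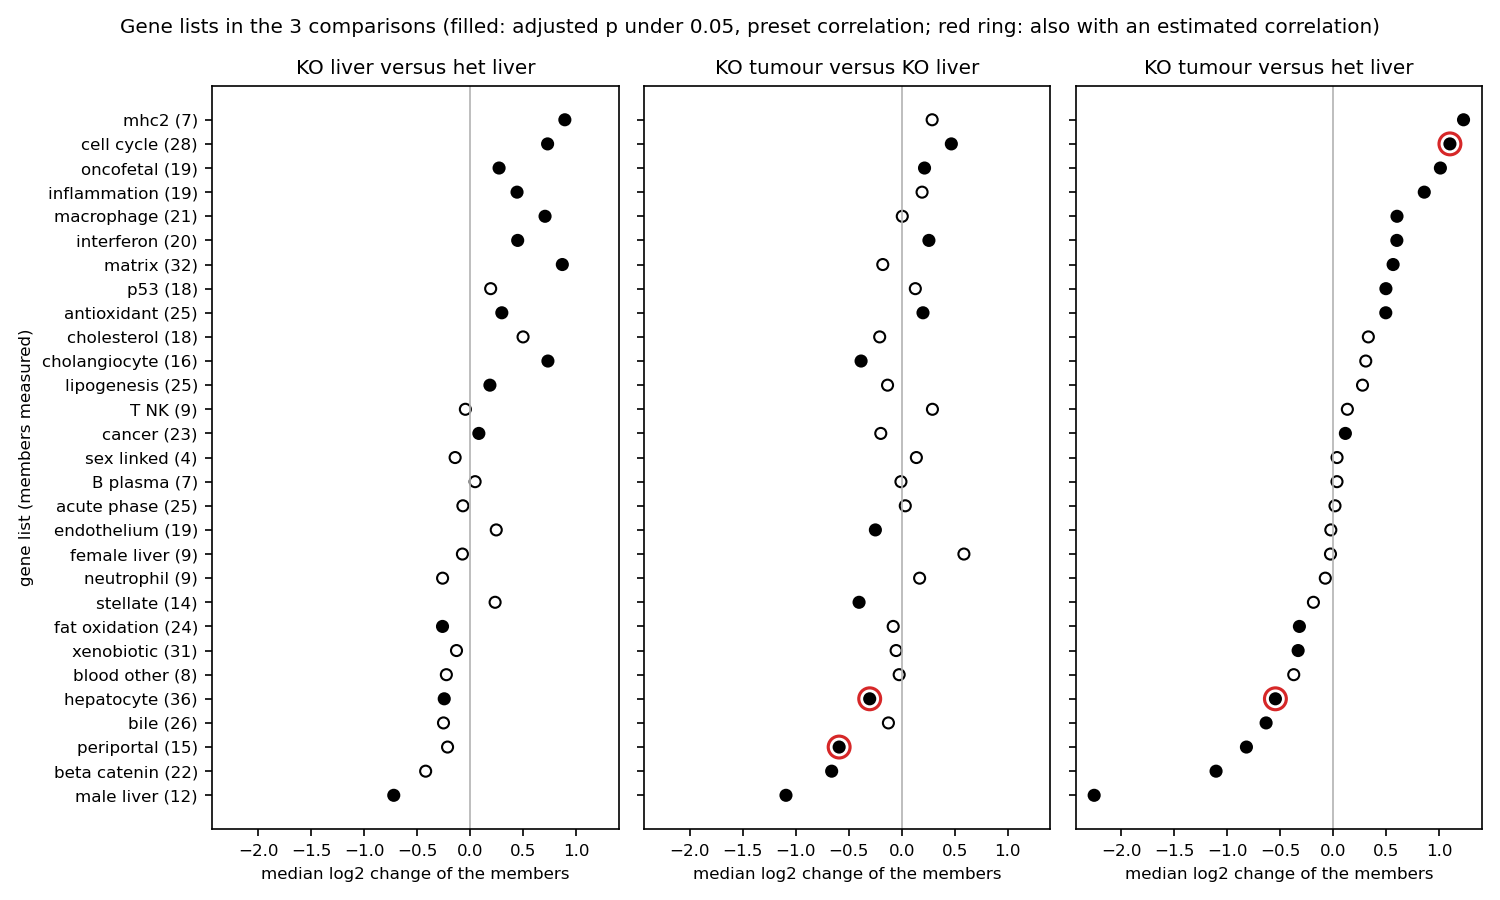
Median log2 change of the tested genes of each of 29 lists in the 3 comparisons; filled points passed an adjusted p of 0.05 with a preset correlation of 0.01 and red rings mark lists that also passed with an estimated correlation. The 2 rings in tumours against knockout livers are hepatocyte and periportal genes, and the 2 in tumours against controls are S phase and mitosis genes and hepatocyte genes.

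The comparison of tumours with control livers asks how the end state differs from liver that is neither knockout nor tumour. On the scale with the added constant, Ly6d was 58.9-fold higher in the tumours (log2 change 5.88 ± 0.65 SE, n = 6 and 3, adjusted p = 6.22e-05), Anxa5 24.3-fold (4.60 ± 0.26 SE, adjusted p = 7.56e-09) and Cd36 rose too (3.91 ± 0.35 SE, adjusted p = 8.91e-06). Lcn2 (4.49), Ubd (3.95), a ubiquitin-like protein, the fatty acid binding protein Fabp4 (3.71), Tubb2a (3.32), a tubulin, Bicc1 (3.26), Lpl (3.20), Tinag (3.16), Lgals3 (3.05), a galectin, and Scd2 (3.04), a fatty acid desaturase, rose too. The lowest probe sets of Fabp4, Tubb2a and Scd2 were at -0.75, 0.67 and 0.76. Hsd3b5 was 102-fold lower (-6.67 ± 1.02 SE, n = 6 and 3, adjusted p = 0.00129), and the organic anion transporter Slc22a7 (-3.95), Ces1e (-3.94), Agxt (-3.52), a peroxisomal enzyme of glyoxylate metabolism, Dio1 (-3.43), Hsd3b2 (-3.05), Susd4 (-2.98), Cnmd (-2.94), Slco1a1 (-2.56), an organic anion transporter, and Ugt3a1 (-2.53) fell. Ly6d, Tinag, Col1a1, Ccnb2, Cidec, Abcb1b, Cdkn1a and Emcn were close to background in the controls, and 4 of 6 tumours had Hsd3b5 signals of 2.2 to 4.7, below the added constant. The folds of these genes are therefore not exact: the log2 change of Ly6d was 7.30 with no constant and 4.78 with a larger one, and that of Hsd3b5 was -8.06 and -5.67. Of 9528 genes, 655 passed, 375 higher and 280 lower, and 417 of them differed at least 2-fold.

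Cell division and matrix genes were higher in the tumours than in the controls. Of 28 genes of S phase and mitosis, 12 rose and 0 fell, and 20 rose when adjusted over the list alone (median log2 change 1.10, adjusted p = 4.60e-12, adjusted p = 0.0480 with an estimated correlation), among them Mcm6 (2.92, with a second probe set at 1.28) and Ccnb2 (2.51). Of 32 matrix genes, 5 rose and 0 fell (median 0.56, adjusted p = 0.000319, adjusted p = 0.413 with an estimated correlation), with the collagens Col4a1 (2.88 ± 0.47 SE, adjusted p = 0.00175) and Col1a1 (2.64 ± 0.62 SE, adjusted p = 0.0156; a second probe set gave 0.29). Of 23 cancer genes, 4 rose and 2 fell (median 0.11, adjusted p = 0.0330, adjusted p = 0.252 with an estimated correlation). Cdkn2c (2.57) and the TGF-beta receptor Tgfbr2 (1.94) rose while the growth factor receptors Egfr (-0.85, with the weakest of 5 probe sets at -0.36) and Erbb3 (-0.67) fell. Of 18 p53 targets, 3 rose (median 0.50, adjusted p = 0.0198, adjusted p = 0.135 with an estimated correlation), with Cdkn1a (2.51, with a second probe set at 0.14) and Btg2 (1.40). Of 19 oncofetal genes, 5 rose (median 1.01, adjusted p = 0.00169, adjusted p = 0.135 with an estimated correlation).

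Macrophage, interferon, inflammation, MHC class II and antioxidant lists were higher too. Of 21 macrophage markers, 6 rose and 0 fell (median log2 change 0.60, adjusted p = 0.00123, adjusted p = 0.337 with an estimated correlation), with Cd68 (1.97 ± 0.25 SE, adjusted p = 0.000226) and Lyz2 (1.93). Of 20 interferon-stimulated genes, 2 rose, Usp18 (2.23) and Ifih1 (1.06) (median 0.60, adjusted p = 0.000274, adjusted p = 0.250 with an estimated correlation). Of 19 inflammation genes, 4 rose, among them Tnfrsf12a (2.94) and the chemokine Ccl6 (1.71) (median 0.86, adjusted p = 0.000366, adjusted p = 0.250 with an estimated correlation). MHC class II genes were higher with 0 of 7 past the test and 3 when adjusted over the list alone (median 1.23, adjusted p = 0.00637, adjusted p = 0.337 with an estimated correlation). Of 25 antioxidant genes, 4 rose (median 0.49, adjusted p = 0.000274, adjusted p = 0.100 with an estimated correlation), with Cbr3 (2.31), a carbonyl reductase, and Srxn1 (1.80, with the lowest of 4 probe sets at -0.05), which reduces peroxiredoxins. Lists of other immune cells did not pass: T and NK cells (median 0.13, adjusted p = 0.868), neutrophils (median -0.08, adjusted p = 0.572) and B and plasma cells (median 0.03, mean -0.21, adjusted p = 0.540), of which Ighm, an antibody heavy chain, fell (-1.11).

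Hepatocyte genes were lower in the tumours than in the controls. Of 36 hepatocyte genes, 11 fell and 0 rose, and 24 fell when adjusted over the list alone (median log2 change -0.55, adjusted p = 1.50e-11, adjusted p = 0.00752 with an estimated correlation), with the coagulation factor F11 (-1.65) and the complement component C8b (-1.52). Of 12 genes higher in male liver, 6 fell (median -2.26, adjusted p = 4.28e-07, adjusted p = 0.115 with an estimated correlation). Of 15 periportal genes, 5 fell and Cdh1 (1.09) rose (median -0.82, adjusted p = 8.66e-05, adjusted p = 0.135 with an estimated correlation). Tat (-1.76) degrades tyrosine and Pck1 (-1.64) makes glucose. Of 22 beta-catenin targets, 2 rose and 3 fell (median -1.11, adjusted p = 0.000346, adjusted p = 0.250 with an estimated correlation). Oat (-2.16) and the glutamate transporter Slc1a2 (-1.78) fell while Gstm3 (2.13) and Ccnd1 (1.53) rose. Of 26 bile genes, 3 rose and 5 fell (median -0.63, adjusted p = 0.0330, adjusted p = 0.404 with an estimated correlation). Slco1a1 and Cyp7b1 (-2.41), of the alternative bile acid pathway, fell while Abcb1a (2.66) rose. Of 31 drug metabolism genes, 7 fell, among them Cyp2c54 (-2.76) (median -0.33, adjusted p = 0.0215, adjusted p = 0.541 with an estimated correlation). Of 24 fat oxidation genes, 1 fell (median -0.32, adjusted p = 0.0330, adjusted p = 0.446 with an estimated correlation). The calls of the bile, drug metabolism and fat oxidation lists were lost with quantile normalization (medians -0.63, -0.21 and -0.25, adjusted p = 0.0727, 0.0881 and 0.158). They were also lost with arrays centred on their medians (-0.70, -0.39 and -0.38, adjusted p = 0.0683, 0.050 and 0.0683). With that centring the list medians lay farther from 0 than in the fit reported here. In the lipogenesis list, which did not pass (adjusted p = 0.298), Cd36 and Cidec (2.68), of lipid droplets, rose while Elovl3 (-2.20), a fatty acid elongase, and Srebf1 (-0.78) fell. Emcn (1.81) of the endothelium list, Tm4sf4 (0.99) of the bile duct list and Ecm1 (-1.26) of the stellate cell list passed singly, and these lists did not (medians -0.02, 0.31 and -0.19).

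The actin 3' to 5' ratio was lower in 6 of 6 tumours than in the controls, and the test did not pass after adjustment (exact two-sided permutation p = 0.0119, adjusted p = 0.0714 over 6 tests). This p is the lowest that the 84 splits of these samples can give. Not passing therefore reflects the few controls and does not show that the ratios are alike. With the actin ratio as a covariate, the count was 21. The log2 changes of the 655 genes then had a median of 0.892 of those without it, 655 of 655 had the same sign, and the median SE grew from 0.27 to 0.45. The lists of male liver, beta-catenin, matrix, MHC class II, oncofetal, cancer, bile, drug metabolism and fat oxidation genes lost their calls. The medians of the last 3 turned to 0.0079, 0.053 and 0.036, and that of MHC class II genes from 1.23 to -0.17. The medians of male liver (-0.73), beta-catenin (-0.47), matrix (0.22), oncofetal (0.11) and cancer genes (0.18) kept their direction. The count of 655 was 249, 247 and 216 without controls 1, 2 and 3, and with these groups alone in the fit it was 117, against 994 in the comparison of knockout livers with controls, so the order of the counts depends on the pooled estimate of the spread. With each array centred on its median, 324 genes were higher and 335 lower. Of the 63 named genes called here (Abcb4 apart), 29 kept their call in every fit without 1 array, among them Ly6d, Anxa5, Cd36, Hsd3b5, Col4a1, Mcm6, Cdkn2c, Cd68 and C8b. Without controls 1, 2 and 3, 27, 33 and 28 of these calls were lost, and without each other array 2 to 9. With the tumours of 1 mouse averaged, the cancer, bile, fat oxidation and drug metabolism lists lost their calls (adjusted p = 0.0618, 0.0924, 0.100 and 0.0799). Drug metabolism lost it with a stricter filter on dim probe sets (median -0.25, adjusted p = 0.0642) and bile with these groups alone in the fit (-0.57, adjusted p = 0.0748). Of the 17 lists, 12 kept theirs in every fit without 1 array. Fat oxidation lost it without tumours 5-1, 5-2 and 6-1 and control 3 (adjusted p = 0.158, 0.120, 0.0520 and 0.0580), drug metabolism without tumours 5-1 and 5-2 and control 3 (0.240, 0.126 and 0.0580), bile without tumours 5-1 and 6-2 and control 3 (0.0822, 0.0504 and 0.0580), p53 without tumour 4 (0.0624) and cancer without tumour 6-1 (0.0520). The values of 1089 genes, 11.4%, did not overlap between the groups, against 2.38% by chance.

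Several named genes have close relatives whose RNA may bind the same probes: Hsd3b5 and Hsd3b2, Abcb1a and Abcb1b, Gstm1 and Gstm3, and the Cyp2 genes. A change of one of these may include that of its relatives.

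Of the genes changed against the controls, 138 were changed in the same direction in knockout livers and in tumours, 114 higher and 24 lower, and 0 in opposite directions; Anxa5, Ly6d, Cd36, Hsd3b5 and Dio1 are among them. Independent lists of these sizes would share 5.12 higher and 0.88 lower genes. Simulated unchanged groups that shared 3 controls shared 0.6 genes on average and at most 4 in 100 draws with the SD of each group, and 0 with pooled SDs. The simulated genes were drawn independently of each other, so these counts do not cover chance overlap from genes that vary together. Both comparisons use the same 3 controls, which are too few to divide between them, so the share of the overlap that the shared controls account for, if any, is unknown. Another 22 genes were called in knockout livers alone and 517 in tumours alone, which does not show that they differ between the tissues; the comparison of tumours with knockout livers called 13 of all 9528 genes. The 138 fell to 31, 44 and 39 without controls 1, 2 and 3, to 77, 75, 66, 58 and 91 without knockout livers 1, 2, 3, 4 and 6, and rose to 208 and 220 without tumours 4 and 5-1.

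The tumours differed more among themselves than the non-tumorous livers did. The median SD of a gene was 0.43 on the log2 scale in tumours, 0.29 in knockout livers and 0.25 in controls, a ratio of tumours to knockout livers of 1.49, and 73.3% of genes had the larger SD in the tumours. Correlations between arrays had a median of 0.909 among tumours and 0.952 among knockout livers. Tumour 5-1 had 807 genes at least 2-fold above and 601 below the mean of the knockout livers, and tumour 6-1 had 146 and 155. No test was run on these values.

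In single tumours, stretches of neighbouring genes moved together. Each sample was compared gene by gene with the mean of the knockout livers, and windows of 41 neighbouring genes were compared with permuted gene orders. Windows past the limit held 738 genes in tumour 3, 860 in tumour 4, 788 in tumour 5-1, 58 in tumour 5-2, 42 in tumour 6-1 and 576 in tumour 6-2, against 0 to 54 in the knockout livers and 0 to 94 in the controls, so 5 of the 6 tumours lay above the highest knockout liver and 4 above the highest control. The table of gene order is that of assembly GRCm38.p6. On chromosome 8, 401 genes from Eri1 to Itgb1 were low in tumour 3 (median log2 ratio -0.51), 287 genes from Cherp to Itgb1 were low in tumour 6-2 (-0.56), and tumour 5-1 had 4 low stretches, the last with 112 genes from Dhx38 to Itgb1 (-0.52). Tumour 6-2 also had 3 high stretches on chromosome 8, of 46, 42 and 79 genes (0.31, 0.34 and 0.33), from Slc10a2 to Smim19, from Tm2d2 to Frg1 and from Tmem192 to Mcm5. The low windows of all 3 tumours shared 239 genes from Ndufb7 to Itgb1. On chromosome 18, 200 genes from Crem to Smad7 were high in tumour 3 (0.77), and in tumour 4 a stretch of 47 genes from Crem to Galnt1 (0.42) and one of 153 genes from Mocos to Ier3ip1 (0.52) were high. Tumour 4 also had high stretches on chromosomes 2, 3, 4, 7, 8, 14 and 16, and tumour 5-1 low stretches on chromosomes 4 and 12. DNA was not measured.

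**Figure D3:**
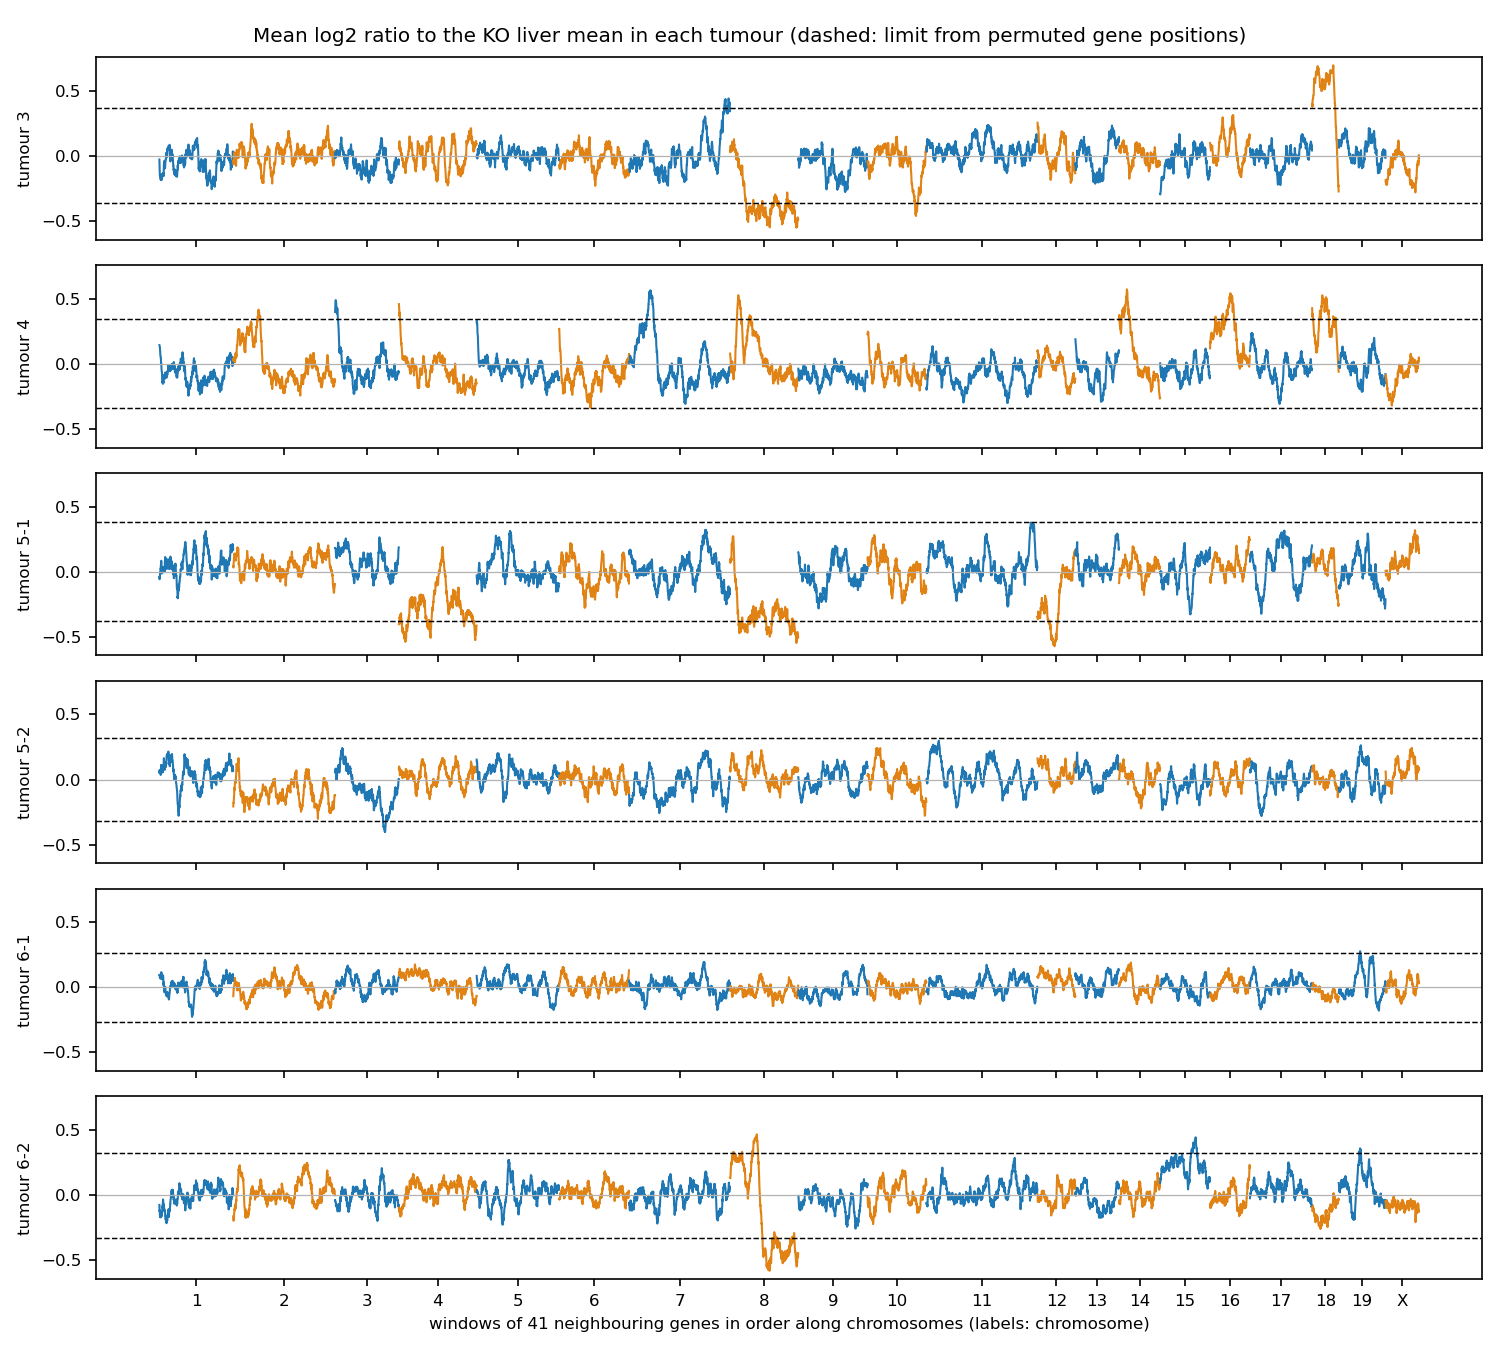
Mean log2 ratio to the knockout livers, each gene limited to between -1 and 1, over windows of 41 neighbouring genes along the chromosomes in each of the 6 tumours; dashed lines are the limits from 1000 permutations of the gene order. Low windows on chromosome 8 are seen in tumours 3, 5-1 and 6-2 and high windows on chromosome 18 in tumours 3 and 4.

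Some of the genes whose values were to be given per sample showed single tumours apart. Cyp2e1 and Eif2s3y, also given below, were not in that set. Afp, alpha-fetoprotein, which adult liver hardly makes, had a signal of 1368 in tumour 5-1 and 724 in tumour 5-2, against 6.2 to 31 in the other tumours, 3.6 to 33.2 in the knockout livers and 4.6 to 6.8 in the controls. Igf2, a fetal growth factor, had 3043 in tumour 5-1 and 10.3 to 34 in the other tumours. As groups these genes did not pass (Afp in tumours against knockout livers, log2 change 1.66 ± 0.92 SE, adjusted p = 0.559; Igf2, 1.29 ± 0.92 SE, adjusted p = 0.669). The beta-catenin targets Glul, glutamine synthetase, and Cyp2e1 had signals of 136 and 846 in tumour 3 and 145 and 812 in tumour 5-1, against at least 513 and 3974 in the other tumours and at least 526 and 6473 in the knockout livers. Tumour 4 had the highest Lgr5 and Axin2 signals of the 15 arrays, 200 and 81.3. Mdm2 signals were 78.8 to 165 in the tumours, 94.2 to 162 in the knockout livers and 100 to 125 in the controls. Those of Mki67 were 18.2 to 116, 4.2 to 49.8 and 5.6 to 23.1. Neither gene passed in tumours against controls (log2 changes 0.13 and 1.35, adjusted p = 0.771 and 0.131). Cdkn1a signals were 45.4 to 274 in the tumours and 8.4 to 27.4 in the controls. Those of Ccnd1 were 182 to 1464 and 199 to 333. The Y-linked gene Eif2s3y had a signal of 51.4 to 143 in every sample, and Xist, which females express, 13.4 to 52.3.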

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

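The tests of the share of hepatocytes, of a few strongly changed genes and of DNA copies, and the use of the actin covariate, were chosen only after the result or the values were seen.

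In 11 of 212 checks of a gene in a group of 6 samples (5.19%), 1 sample lay far from the other 5, and chance gives about 1 in 20. In the knockout livers these were Acaa1b in liver 1 (log2 value 12.62, low), Agxt in liver 6 (8.26, low), Cnmd and Lgals3 in liver 5 (6.43, high, and 7.56, low) and Pdgfrb in liver 3 (7.94, high). In the tumours they were Ccnd1, Igf2 and Pcna in tumour 5-1 (7.58, low, 11.58, high, and 10.55, high), Erbb3 in tumour 3 (8.74, low), Lgr5 in tumour 4 (7.71, high) and Susd4 in tumour 6-1 (5.45, high). Of 58 checks of list scores, 4 (6.90%) did so, near the share chance gives: S phase and mitosis genes and lipogenesis genes in knockout liver 1 (-0.52 and -0.33 against the mean of the knockout livers) and interferon and macrophage genes in tumour 4 (-0.60 and -1.30). Of 20 checks of array measures, 3 (15%) did so: the 40th percentile of the signal in tumour 4 (22.6) and the signals of the 3' and 5' probe sets of 18S ribosomal RNA in knockout liver 2 (2583 and 6027). No explanation of these values was tested.

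Other splits of the same samples were fitted in each comparison. Between knockout livers and controls, where every sample is from a different mouse, they argue against chance as the whole source of the count. Between knockout livers and controls, 1 of 84 splits, the real one, gave as many as 160 genes, and the highest other gave 2. Between tumours and knockout livers, 1 of 100 splits drawn from 462, the real one, gave as many as 13 genes, and the highest other gave 2. These splits ignore that 4 mice gave both tissues. Only 12 splits part every matched pair, too few for a share under 0.05; 1 of them, the real one, gave as many (8.33%), and the highest other gave 0 in limma. Between tumours and controls, 1 of 84 splits, the real one, gave as many as 655 genes, while the highest other gave 296. That other split set tumours 5-1, 5-2 and 6-2 against the controls with tumours 3, 4 and 6-1. These splits treat the 6 tumours as separate animals although 2 mice gave 2 tumours each, so they cannot exclude chance for this count.

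The first pattern weighed is the stretch of chromosome 8 with lower values in tumours 3, 5-1 and 6-2. A few strongly changed genes are argued against: every other gene was used to find the low windows, and the 147 to 233 genes between them had medians of -0.58 to -0.42 over the 3 tumours and either set of genes (bootstrap upper bounds -0.43 to -0.28), below every knockout liver on the same genes (lowest -0.12). This was the last of 3 tests tried: one on the shared genes was dropped because they had been picked for low values, and one on the share of genes below 0 among those under 2-fold (68.0% to 77.1%) missed its bound in 1 of 6 checks, in tumour 6-2, where the bootstrap lower bound of 60.4% did not pass the highest knockout liver, 61.6%. As to array scaling, 100% of the stretch stayed in low windows after quantile normalization. Each sample had already been centred on its median, and scaling acts without regard to gene position. This check could therefore hardly have come out otherwise, and no conclusion is drawn from it. Loss of DNA copies may lower such a stretch; the lowest fold of its median was 0.670, which other causes can give, and since DNA was not measured this cannot be told apart from regulation of the genes.

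The second pattern is the set of 160 genes changed between knockout livers and controls, beside the actin ratio, which was lower in knockout livers than in controls (adjusted p = 0.0714). With the actin ratio as a covariate, the log2 changes had a median of 0.949 of those without it (bootstrap 0.917 to 0.992), above the bound of 0.5 set for RNA quality as the whole cause, and 160 of 160 had the same sign. Only 18 of them still passed the test, as the median SE grew from 0.30 to 0.42, while 151 had an unadjusted p under 0.05 in limma. The actin ratio is 1 measure of RNA quality, and the 160 genes were picked from the fit without it. These values therefore do not exclude RNA quality as the whole cause. RNA quality could also explain single lists, such as genes higher in male liver, whose median went from -0.72 to 0.08, and MHC class II genes, from 0.89 to -0.11. The genotype and other differences between the mice remain open and untested.

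The third pattern is the lower level of hepatocyte genes in tumours than in knockout livers (median -0.30, bootstrap -0.42 to -0.20). A lower share of hepatocytes would raise the markers of the other cell types alike only if these types kept their proportions to each other. The endothelium list went down (-0.25, bootstrap over genes -0.53 to -0.04) and the T and NK cell list up (0.29, bootstrap 0.13 to 0.42). These were the only lists of another cell type whose intervals left out 0. The intervals were -0.68 to 0.07 for stellate cells, -0.80 to 0.09 for bile ducts and -0.17 to 0.12 for macrophages. For B and plasma cells the interval was -0.51 to 0.13 and for neutrophils -0.31 to 0.35. The endothelium and T and NK cell values go against such an even rise. They cannot decide on a lower share in which some other cell types rise and others fall. The endothelium call ended without tumour 4 or tumour 6-1 (medians -0.12 and -0.11, adjusted p = 0.0906 and 0.188). The bootstrap is over genes rather than samples, so the evidence is weak. Of the tested members, 14 of 19 endothelium, 3 of 9 T and NK cell, 17 of 21 macrophage, 12 of 14 stellate cell and 6 of 16 bile duct genes lay above the 40th percentile in control liver, and 4 bile duct and 2 hepatocyte genes are in another list. A lower share of hepatocytes and a change of state of the tumour hepatocytes both remain hypotheses, and the second was not tested.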

How the results depend on the processing

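The covariate for the actin 3' to 5' ratio was chosen after the values were seen; the other alternatives were set before. Where a value below changed, the cause was not tested, except that a stricter threshold, a fold minimum, more probe sets or fewer samples change a count by their construction.

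Against controls, the 160 genes changed in knockout livers became 350 with tumours of 1 animal averaged, 293 with all kept probe sets, 851 with array weights, 994 with the compared groups alone, 32 at an adjusted p under 0.01, 21 with the actin covariate, and 34 to 298 without single arrays. The 655 genes changed in tumours became 1031 with all kept probe sets, 117 with the compared groups alone, 186 at an adjusted p under 0.01, 417 with a 2-fold minimum, 21 with the actin covariate, and 216 to 782 without single arrays. The 138 genes changed in both became 256 with tumours averaged, 246 with all kept probe sets, 479 with array weights, 12 with the actin covariate, and 31 to 220 without single arrays.

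Between tumours and knockout livers, the 13 genes became 0 with the replicate block as a fixed term in matched animals, 49 with tumours averaged, 4 with no pseudocount, 20 with all kept probe sets, 8 with array weights, 0 with the compared groups alone, 0 at an adjusted p under 0.01, 7 with a 2-fold minimum, 0 with the actin covariate, and 0 to 62 without single arrays; the zeros are from limma, with 731 to 1098 genes at an unadjusted p under 0.05.

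Lists called fell from 14, 11 and 17 to 0, 2 and 2 with an estimated correlation, and to 8, 10 and 9 with the actin covariate. With tumours averaged, 2 lists between tumours and knockout livers and 4 between tumours and controls lost their calls. Without single arrays they were 12 to 19, 9 to 12 and 14 to 19. With the actin covariate and against controls, medians changed sign in knockout livers for male liver (-0.72 to 0.08), MHC class II (0.89 to -0.11) and oncofetal genes (0.27 to -0.18). They did so in tumours for MHC class II (1.23 to -0.17), bile (to 0.0079), fat oxidation (to 0.036) and drug metabolism (to 0.053). For fat oxidation in knockout livers the test changed sign and the median stayed below 0 (-0.032). Abcb4 in knockout livers went from -1.89 to -1.21 with the actin covariate (adjusted p = 0.310), and to between -1.98 and -1.80 without single arrays. The ratio of spreads stayed between 1.36 and 1.58, and 4 or 5 tumours lay above the highest knockout liver in windows.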

Other observations

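The list scores and windows set side by side in this part were picked after the values were seen, and no test was run on them.

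Tumours 5-1 and 5-2, from 1 mouse by the labels, differed in list scores, given as mean log2 ratios to the knockout livers. Cholesterol synthesis genes were at -2.10 in tumour 5-1 and at 2.08 in tumour 5-2, with the other tumours between -1.08 and 0.62. Lipogenesis genes were at -1.42 and 0.11, and MHC class II genes at 1.83 and 0.44. Oncofetal genes were at 1.62 and 1.20, against -0.21 to 0.43 in the other tumours.

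Tumour 4 had a macrophage score of -1.30 and a matrix score of -0.92, each the lowest of the tumours. In tumours 3 and 5-1 the beta-catenin scores were -1.13 and -1.64 and the male liver scores -1.89 and -2.73.

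In the windows along chromosomes, control 1 had 47 low genes on chromosome X, from Gprasp1 to Phka2 (median log2 ratio -0.38), and control 2 had 43, from Gprasp1 to Rps6ka3 (-0.28), and 51 on chromosome 18, from Myo7b to Diaph1 (-0.40).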
